A study of Mus musculus with 426 samples.

How the data were processed

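RNA and DNA were read from 420 single cells and 6 bulk samples of a mouse pancreatic tumour model, all from 3 mice. Per the labels, cells were sorted by fluorescence, their complementary DNA was amplified in the manner of SMART-Seq2, and their genomes were then amplified with the SeqXE kit in the same tube. Per the submitters' processing notes, reads were divided into exonic reads, taken as RNA, and nonexonic reads, taken as DNA. Those notes name STAR, kallisto and Bowtie 1.0 and the mouse build mm9 without a role for each, so which tool made which file is not given in the sources used here. The RNA file holds expected counts per gene as deposited by the authors, of which 97.35% were exactly whole numbers. The DNA file holds counts in 5000 genomic bins, as deposited by the authors: 4730 autosomal, 267 on X and 3 on Y.

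Of 24520 rows of the RNA file, 92 ERCC spike-in rows (0.000348% of counts) and 4 rows with a repeated symbol were left out, which left 24424. A further 27 symbols read as dates and were kept as deposited. Within groups of a mouse 2946 pairs of libraries were compared by the chi-square per degree of freedom of their DNA counts. In peritoneum of mouse 1, cells 37 and 46 (0.735) and cells 38 and 47 (0.854) differed by less than sampling noise, the lowest of the other pairs being 1.61 and their median 15.6. The log RNA correlation of these 2 pairs was 0.933 and 0.954, but the same chi-square of their RNA counts was 19.1 and 3.94, above sampling noise, so that they are 1 library is not certain. Each pair was counted as 1 cell, which left 418 cells. RNA was analysed in 368 cells with at least 500 detected genes and 10000 counts (strict alternative: 2000 genes and 50000 counts, 324 cells). Kept cells had 10805 to 17845615 RNA counts. DNA was analysed in 410 cells with a read on every chromosome, leaving out 8, and 318 cells had at least 50000 DNA reads, with a median of 584486 reads or 117.0 per bin.

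Counts of kept cells were summed per mouse and group and rounded to whole numbers. The sums ran from 535494 to 84356250, and a single cell gave 75.3% of the liver sum of mouse 2 and 63.3% of the EpCAM+ sum of mouse 2. Genes were filtered with edgeR's default filter, scaled with TMM and tested with edgeR 4.0.16 quasi-likelihood fits, with 1 fit for the 4 primary sorts (19703 genes, biological coefficient of variation 1.16) and 1 for GFP+ cells of the primary tumour and the 4 sites (21988 genes, 1.08). P-values were adjusted by Benjamini-Hochberg within a comparison at 0.05. The replicate was the mouse. Groups, comparisons and most of the alternatives were fixed before the data were examined. Those alternatives were DESeq2 1.42.0, scaling by library totals without TMM, other cell and gene filters, each cell weighted alike (limma 3.58.1 on means of log2(CPM+1) or log2(CPM+0.1)), a fit of only the groups compared, a block for the mouse and leaving out a mouse. In fits without a mouse some groups keep 1 sample, and edgeR and limma then take their error from the other groups.

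Mouse numbers in the labels pair samples of the same animal, and the fits reported hold no block for the mouse, which was an alternative. As a check, deviations from the group means of log2 CPM had a median correlation, between sums of the same mouse, of 0.0962 (0.0286 to 0.220) in the primary sorts, against -0.068 for other mice, and 0.0451 (-0.137 to 0.352) against -0.0451 in the fit of sites. DESeq2 and TMM scale the sums differently. The median log2 difference of all genes was 0.20 with TMM, 0.94 with DESeq2 and 0.37 without TMM for CD45+ against GFP+ cells. The same 3 values were 0.07, 0.61 and 0.13 for EpCAM+, -0.23, 0.02 and -0.80 for GFP+EpCAM+, and 0.30, 0.60 and 0.90 for EpCAM+ against GFP+EpCAM+ cells. They were 0.08, 0.18 and 0.60 for peritoneum, -0.10, 0.01 and 0.09 for kidney, -0.61, -0.11 and 0.22 for liver, 0.01, 0.00 and 0.28 for spleen, and -0.23, 0.01 and 0.23 for the mean of sites.

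Genes were named by a rule fixed in advance. Ptprc, Epcam, Krt19 and Vim were given for each comparison with a log2 difference. In each direction up to 8 called genes with the largest difference were given, with a mean of at least 10 CPM over the groups and the same direction in every mouse having both groups, leaving out predicted genes and Y-linked genes. From each of the 6 called lists with the smallest p, or fewer, up to 3 genes with the smallest p were added. Some items are withheld for evaluations and their results are left out. A group with 0 counts was given a floor of 3 counts over the group. Gene lists were written from general knowledge before the test: pan-leukocyte, macrophage and monocyte, neutrophil, T and natural killer cell, B cell, dendritic cell, MHC class I and II, epithelial, mesenchymal transition, fibroblast and stellate, endothelial, acinar, islet, hepatocyte, kidney tubule, mesothelial, erythroid, classical and basal-like pancreatic tumour, proliferation, hypoxia and glycolysis, interferon response, immediate early and heat shock, unfolded protein response, cholesterol synthesis, oxidative phosphorylation, cytosolic ribosomal protein, chemokine and inflammatory, adhesion and invasion, and tumour genotype. Lists with at least 5 tested genes were tested on voom values with camera of limma, with its preset correlation of 0.01 and with an estimated one, and with fry of the same package, and p-values were adjusted over the lists of a comparison (29 in the primary sorts, 31 for sites). Members were counted with p adjusted over all genes and adjusted over the list alone.

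DNA counts of a cell were taken as log2 of the mean coverage of a chromosome relative to the autosomal mean, averaged over cells per mouse and group, and tested with limma over 19 autosomes and X. Alternatives were the median over bins as centre or per chromosome, leaving out 237 unstable bins, leaving out the cells with the most noise (309 cells left), a block for the mouse and leaving out a mouse. Score tests were exact permutation tests of mouse means, with exact sign-flip tests of differences within a mouse as an alternative. The limit of 0.171 for the tumour pattern was the 95th percentile of CD45+ cells. Percentages of cells have exact Clopper-Pearson 95% intervals. Expression against DNA used the median log2 difference of the genes of a chromosome, with gene positions of the mouse assembly GRCm38.p6 for 95.9% of tested genes (18882 genes on the chromosomes used), and 100000 permutations.

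On simulated data with no change the RNA fits made 0 false calls. With 200 changed genes they made 0 for CD45+ against GFP+ cells, 3 for peritoneum and 8 for the mean of sites, and 18% of genes changed 256-fold and 0% of those changed 16-fold were recovered for CD45+ against GFP+ cells, 70% and 8% for peritoneum, and 96% and 22% for the mean of sites. The simulated RNA counts were drawn for each gene independently and held no effect of the mouse. Other groupings of the real sums that ignored the mouse gave a median of 236 calls for the mean of sites. The simulated count of false calls therefore need not hold for the real sums. A DNA shift of 0.3 was recovered in 100% of 100 simulations, with 1.19% false calls. DNA reads counted as exonic were gauged by 1125 olfactory receptor genes, whose share followed the DNA to RNA ratio of a cell (Spearman rho 0.940 over 368 cells). Their median CPM per gene was 0.0604 in spleen, 0.0856 in GFP+EpCAM+, 0.190 in GFP+, 0.277 in EpCAM+, 0.483 in peritoneum, 0.742 in CD45+, 1.43 in kidney and 1.90 in liver cells, and levels near or below these are not told from stray DNA reads. Of 43 shallow kept libraries, 6 had an RNA correlation above 0.8 with a library of the same mouse at least 20 times deeper.

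Settings chosen after the data were seen were cells with at least 50000 DNA reads, the median settings in those cells, genes of at least 100 CPM on average or in both groups, scores in pairs, groupings within the mice with the block, liver left out, means over cells with a block, the relation of expression to DNA within 2 sets of chromosomes, and RNA of 4 Y genes (Ddx3y, Eif2s3y, Kdm5d and Uty) against 5 taken as silent outside the testis (Sry, Zfy1, Zfy2, Usp9y and Uba1y). A test that ranked kidney cells by their own leukocyte RNA was computed and then left out, because it selected cells by the outcome. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and its package data.table, version 1.17.8.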

Results

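Messenger RNA and genomic DNA were read from the same single cells of a mouse pancreatic cancer model by GTO, a method that amplifies the complementary DNA and then the genome of a cell in a single tube. The tumours had grown for 6 to 8 weeks from 50000 injected KPC1199-EGFP cells, a mouse pancreatic tumour line that carries green fluorescent protein (GFP), in the pancreas of C57BL/6 males. Cells of the primary tumours of 3 mice were sorted by GFP, by the epithelial surface protein EpCAM, by both (GFP+EpCAM+) or by CD45, the pan-leukocyte surface protein. GFP+ cells were also sorted from peritoneal metastases of the 3 mice and from kidney, liver and spleen metastases of mice 2 and 3. The 420 single-cell libraries (418 cells, since 2 pairs of libraries were counted as 1 cell each) comprised 96 GFP+, 28 EpCAM+, 33 GFP+EpCAM+ and 58 CD45+ cells of the primary tumour, and 86 peritoneum, 44 kidney, 33 liver and 40 spleen cells. The 6 bulk libraries enter no test here. Expected RNA counts ran from 3 to 17845615 per library, and DNA counts from 5 to 3255873.

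Of the single cells, 368 passed the RNA filter of 500 detected genes and 10000 counts, with a median of 1016775 RNA counts. The cells that passed numbered 76 GFP+, 25 EpCAM+, 31 GFP+EpCAM+ and 56 CD45+ in the primary tumour, and 85 in peritoneum, 44 in kidney, 16 in liver and 35 in spleen. Before that filter the median RNA total was 859257 in GFP+, 998481 in EpCAM+, 1874539 in GFP+EpCAM+, 727090 in CD45+, 780859 in peritoneum, 522487 in kidney, 9269 in liver and 488332 in spleen cells. The median DNA total was 276652 in GFP+, 561691 in EpCAM+, 431296 in GFP+EpCAM+, 773082 in CD45+, 602993 in peritoneum, 381353 in kidney, 5987 in liver and 274155 in spleen cells. Values per group are means over mice with the standard deviation (SD) over mice. RNA levels are counts scaled to a library of 1e+06 (CPM) of the counts summed per mouse and group. Confidence intervals and count floors cover counting error only, because amplified reads are not independent molecules.

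CD45+ cells were compared with GFP+ cells to set the leukocytes of the primary tumour against cells of the injected line. CD45+ cells carried more RNA of macrophage, T cell, natural killer cell and neutrophil genes and of the MHC class II genes that present antigen, and less RNA of the matrix genes Lum, Col3a1 and Sparc. Lyz2, the lysozyme of myeloid cells, stood at 12542 ± 3387 CPM in CD45+ and 5.75 ± 5.51 CPM in GFP+ cells (SD, n = 3 mice each; log2 difference 11.09, SE 1.60, edgeR adjusted p = 5.10e-04). Lum, the collagen-binding proteoglycan lumican, stood at 5.39 ± 4.02 CPM in CD45+ and 1716 ± 1458 CPM in GFP+ cells (log2 difference -8.32, SE 1.86, adjusted p = 0.0284). Each of these differences had the same direction in 3 of 3 mice. Of 19703 genes tested, 123 were higher and 37 lower in CD45+ cells.

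Macrophage and monocyte genes rose as a list: 10 of 14 members were higher over all genes tested and 13 when adjusted over the list alone (camera adjusted p = 1.85e-25, adjusted p = 0.00934 with an estimated correlation). Fcgr3, a receptor for immunoglobulin G, rose by 11.19 on the log2 scale to 5653 ± 2685 CPM, and the complement genes C1qa and C1qb rose by 11.81 and 10.39. Of 12 pan-leukocyte genes 6 were higher and 10 were so adjusted over the list alone (camera adjusted p = 2.94e-19, adjusted p = 0.0121 with an estimated correlation). Ptprc, which encodes CD45 itself, stood at 329 ± 244 CPM against 1.32 ± 0.526 CPM (log2 difference 7.95, SE 1.89, adjusted p = 0.0383). The actin-bundling Lcp1, the granule proteoglycan Srgn and the Fc receptor chain Fcer1g rose by 9.47, 10.12 and 7.42. Of 7 MHC class II genes 5 were higher and 7 were so adjusted over the list alone (camera adjusted p = 7.39e-14, adjusted p = 0.0121 with an estimated correlation), with H2-Eb1 at 11.55, H2-Ab1 at 9.88 and H2-Aa at 7.33.

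Of 13 T and natural killer cell genes 7 were higher and 9 were so adjusted over the list alone (camera adjusted p = 1.45e-13, adjusted p = 0.00116 with an estimated correlation), among them the cytotoxic granule gene Nkg7 (log2 difference 12.20), the T cell receptor chain Cd3e (10.55) and the kinase Lck (9.34). Of 9 neutrophil genes 5 were higher and 8 were so adjusted over the list alone (camera adjusted p = 2.23e-11, adjusted p = 0.0143 with an estimated correlation). The cytokine Il1b reached 12950 ± 10593 CPM (log2 difference 10.61), and Clec4d and the receptor Csf3r rose by 9.95 and 9.48. Among the other genes with the largest rises were the platelet chemokine Ppbp (14.40), the chemokine Ccl4 (12.31), the lipase inhibitor G0s2 (11.91) and the immunoglobulin receptor Fcgr4 (11.89). In CD45+ cells Ppbp stood at 2063 ± 3572, G0s2 at 1294 ± 1973 and Fcgr4 at 862 ± 1485 CPM. Their SDs exceed their means, so these levels were uneven over the mice. With the mouse as a block Ppbp (10.68, edgeR adjusted p = 0.117) and Fcgr4 (10.59, adjusted p = 0.120) were not called. Mrgpra2b was at least 17566-fold higher, since GFP+ cells had 0 counts (floor of 3 counts over the group), and Pira4 rose by 13.22. Both belong to families of near-identical genes, so their reads are uncertain.

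Fibroblast and stellate genes fell: 6 of 16 were lower (Lum, Col3a1, Sparc, Col6a1, Postn and Dcn) and 14 were so adjusted over the list alone, with a median log2 difference of -6.76 (camera adjusted p = 6.86e-12, adjusted p = 0.132 with an estimated correlation). The collagen Col3a1 stood at 12.1 ± 12.8 CPM against 1982 ± 1738 CPM, and the matrix protein Sparc fell by 7.28 on the log2 scale. Outside that list, Pcolce, an enhancer of procollagen processing, was lower (log2 difference -8.73), as were the matricellular Thbs2 (-8.47), Serpinf1 (-8.41), Mxra8 (-8.26), the bone morphogenetic protein antagonist Grem1 (-8.18) and the matricellular Cyr61 (-7.95). With the mouse as a block Thbs2 (-6.47, edgeR adjusted p = 0.0852) and Mxra8 (-7.27, adjusted p = 0.0840) were not called. Tmem254c was at least 1307-fold lower, with 0 counts in CD45+ cells, and is uncertain because near-identical copies share its reads. Epcam (log2 difference 1.17, adjusted p = 0.606), Krt19 (-0.40, adjusted p = 0.879) and Vim (-1.40, adjusted p = 0.502), by edgeR, did not pass the test.

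With the preset correlation 17 of 29 lists passed camera's test in this comparison, and 5 did so with an estimated correlation. Lists that passed only with the preset one were higher for B cell genes (8 genes; adjusted p = 0.0201, adjusted p = 0.321 with an estimated correlation), MHC class I (9; 0.0228, adjusted p = 0.321 with an estimated correlation), interferon response (22; 0.0341, adjusted p = 0.412 with an estimated correlation) and dendritic cells (10; 0.0358, adjusted p = 0.321 with an estimated correlation). The last was not called with the mouse as a block (adjusted p = 0.0889), and the chemokine receptor Ccr7 was its only member called over all genes. Adjusted over the list alone, 3 B cell, 2 MHC class I, 1 interferon and 2 dendritic cell genes were higher. Lists that were lower were proliferation (26 genes, median -2.08; adjusted p = 1.67e-06, adjusted p = 0.321 with an estimated correlation), cytosolic ribosomal proteins (23, median -1.19; 1.14e-04, adjusted p = 0.418 with an estimated correlation), unfolded protein response (15; 0.0201, adjusted p = 0.355 with an estimated correlation), oxidative phosphorylation (22; 0.0228, adjusted p = 0.473 with an estimated correlation) and mesenchymal transition (19; 0.0228, adjusted p = 0.462 with an estimated correlation). In the last of these 1 gene was higher, Tgfbi, and 5 were lower adjusted over the list alone.

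Immediate early and heat shock genes (18 genes, adjusted p = 0.0228, adjusted p = 0.468 with an estimated correlation; 0.0526 with the mouse as a block) and cholesterol synthesis genes (15, 0.0359, adjusted p = 0.321 with an estimated correlation) were also lower by camera. Their median log2 differences of -0.25 and -0.74 turned to 0.51 and 0.04 with DESeq2's scaling, which moved the median of all genes from 0.20 to 0.94. Tumour genotype genes (10) had an adjusted p of 0.0589, and 0.0453 with the mouse as a block. The lists not called were hepatocyte (adjusted p = 0.116), chemokine and inflammatory (0.148), endothelial (0.238), classical pancreatic tumour (0.259), kidney tubule (0.322), epithelial (0.415), adhesion and invasion (0.419), mesothelial (0.590), hypoxia and glycolysis (0.590), basal-like pancreatic tumour (0.643) and acinar (0.712). Adjusted over the list alone, the epithelial genes Lcn2 and Spint1 were higher and 3 classical tumour genes lower (Sox9, Onecut2 and Ctse), while the epithelial median (-0.17) and mean (0.62) differed in sign. The count of 160 called genes fell to 38 without mouse 2 and to 11 without mouse 3, and DESeq2 called 917 higher and 998 lower.

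**Figure D1:**
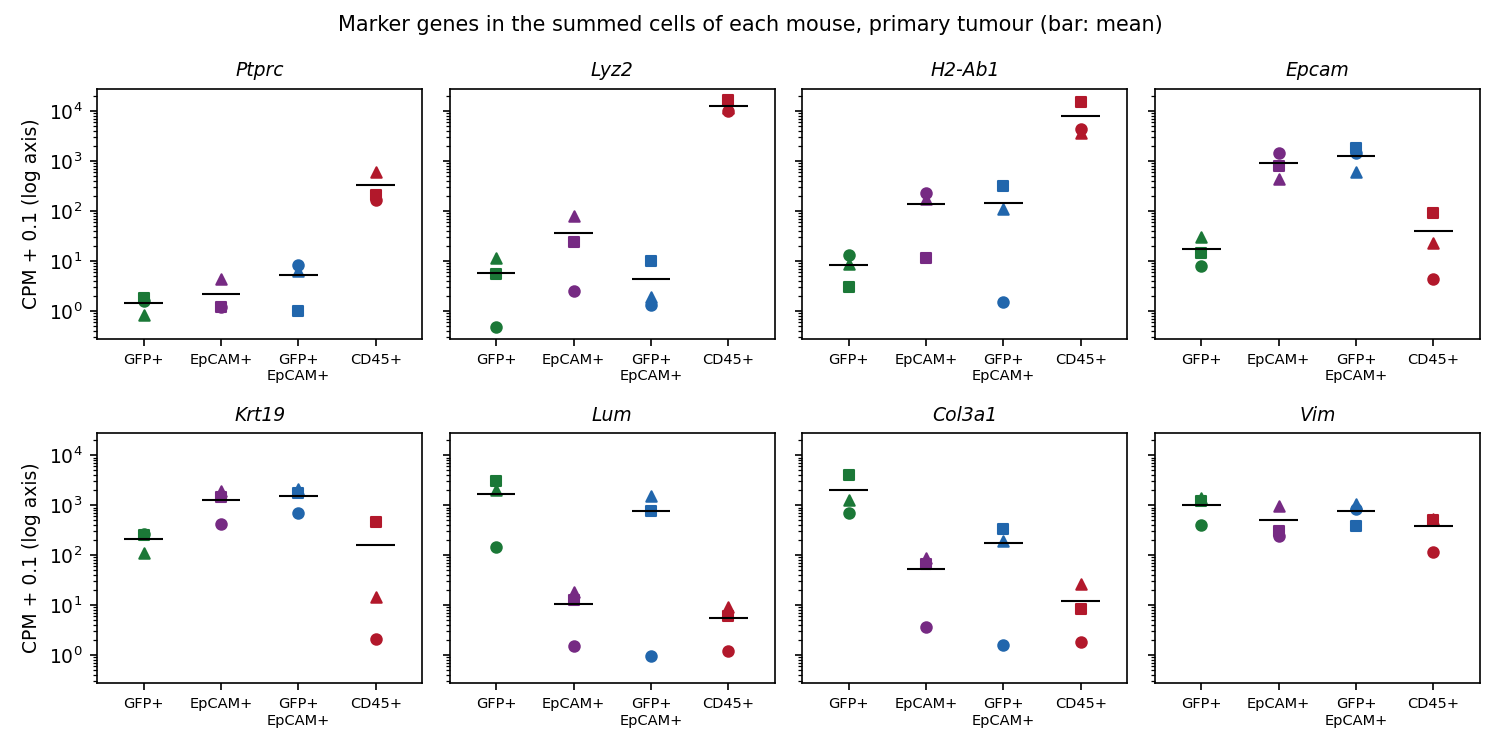
RNA levels of 8 marker genes in the 4 sorts of the primary tumour, in CPM + 0.1 on a log axis; points are mice (circle 1, square 2, triangle 3) and bars are means over 3 mice. Ptprc, Lyz2 and H2-Ab1 stand highest in CD45+ cells, Epcam in EpCAM+ (893 CPM) and GFP+EpCAM+ cells (1286 CPM), and Lum and Col3a1 in GFP+ cells.

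EpCAM+ cells were compared with GFP+ cells to ask how sorting by an epithelial surface protein and by the tumour label differ. Epcam stood at 893 ± 507 CPM in EpCAM+ and 17.6 ± 11.6 CPM in GFP+ cells (SD, n = 3 each), higher in 3 of 3 mice, and Lum at 10.7 ± 8.47 against 1716 ± 1458 CPM, lower in 3 of 3 mice. Neither passed edgeR's test over all genes (log2 differences 5.67 and -7.33, SE 1.34 and 1.79, adjusted p = 0.350 for each). Fibroblast and stellate genes had a median log2 difference of -5.94, and 13 of 16 were lower adjusted over the list alone, among them Postn (-8.58) and the collagen Col6a1 (-6.49). Epithelial genes had a median of 2.82, and 9 of 20 were higher adjusted over the list alone, among them the protease St14 (7.35) and the keratin Krt7 (3.72). Krt19 stood at 1273 ± 771 against 210.0 ± 86.4 CPM (log2 difference 2.60, adjusted p = 0.443).

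Camera called 7 of 29 lists with the preset correlation and 0 with an estimated one. Fibroblast and stellate genes were lower (adjusted p = 8.45e-17, adjusted p = 0.105 with an estimated correlation), and epithelial genes higher (2.82e-11, adjusted p = 0.105 with an estimated correlation). Classical pancreatic tumour genes were higher (2.21e-05, adjusted p = 0.105 with an estimated correlation), with 2 of 14 higher adjusted over the list alone, the secreted-protein isomerase Agr2 (7.74) and the transcription factor Hnf4a (6.30), while Tff1 (8.44) did not pass. Mesenchymal transition genes were lower (5.85e-04, adjusted p = 0.811 with an estimated correlation) with 0 of 19 called, and Tgfbi, Snai2 and Axl had log2 differences of -4.82, -6.31 and -3.97. Proliferation genes were lower (0.0151, adjusted p = 0.962 with an estimated correlation) with 0 of 26 called; their median of -0.32 turned to 0.50 with DESeq2's scaling, which moved the median of all genes from 0.07 to 0.61. Bub1, Tk1 and Rrm2 had log2 differences of -3.70, -2.98 and -2.51.

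Macrophage genes (adjusted p = 0.0320, adjusted p = 0.866 with an estimated correlation) and MHC class II genes (0.0428, adjusted p = 0.811 with an estimated correlation; 0.0567 with the mouse as a block) were higher as lists. Adjusted over the list alone, the complement gene C1qc was higher (4.76) and the lysosomal Cd68 lower (-6.79), Lyz2 did not pass (2.62), and 2 MHC class II genes were higher, H2-Eb1 and H2-Ab1. The other lists had adjusted p between 0.169 and 0.959. Vim (-1.02) and Ptprc (0.66) had adjusted p of 0.806 and 0.930. Over all genes edgeR called 0 of 19703, with 2235 at an unadjusted p under 0.05, while DESeq2 called 298 higher and 572 lower, and limma on means over cells called 4.

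GFP+EpCAM+ cells were compared with GFP+ cells to ask how tumour cells that also carry EpCAM differ from all GFP+ cells. Epcam stood at 1286 ± 627 against 17.6 ± 11.6 CPM (log2 difference 6.19, SE 1.38, edgeR adjusted p = 0.281) and the mucin Muc1 at 7444 ± 7373 against 478 ± 253 CPM (3.96, SE 1.10, adjusted p = 0.281), each higher in 3 of 3 mice (n = 3 each). Of 20 epithelial genes 7 were higher adjusted over the list alone, with a median of 3.30, among them the lipocalin Lcn2 (7.60). Postn, a matrix protein of fibroblasts, had a log2 difference of -10.06, Col5a1 -7.13 and Col1a2 -5.53, and 4 of 16 fibroblast and stellate genes were lower adjusted over the list alone. MHC class II genes had a median of 2.91 with 4 of 7 higher adjusted over the list alone, among them H2-Eb1 at 65.7 ± 15.2 against 1.10 ± 0.294 CPM (5.90), H2-Ab1 (4.10), H2-DMb1 (3.74) and Cd74 (2.91).

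Camera called 13 of 29 lists with the preset correlation, of which 2 held with an estimated one: epithelial genes (adjusted p = 1.01e-19, adjusted p = 0.0194 with an estimated correlation) and classical pancreatic tumour genes (5.02e-08, adjusted p = 0.0311 with an estimated correlation), both higher. In the classical list, with 0 of 14 called adjusted over the list alone, the trefoil factor Tff2, Onecut2 and Hnf4a had log2 differences of 5.99, 2.74 and 5.14. Fibroblast genes were lower (6.12e-15, adjusted p = 0.138 with an estimated correlation) and MHC class II genes higher (9.99e-06, adjusted p = 0.156 with an estimated correlation). Immediate early and heat shock genes were higher as a list (0.0016, adjusted p = 0.528 with an estimated correlation), as were unfolded protein response genes (0.00267, adjusted p = 0.410 with an estimated correlation), with 0 called in either. Their members Atf3 (3.20), Klf4 (2.89), Herpud1 (2.28), Xbp1 (2.30) and Dnajb9 (3.26) had positive and the chaperone Hsph1 (-3.43) a negative log2 difference.

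MHC class I (0.00777, adjusted p = 0.243 with an estimated correlation), chemokine (0.0149, adjusted p = 0.215 with an estimated correlation) and adhesion genes (0.0247, adjusted p = 0.243 with an estimated correlation) were higher as lists. So were hypoxia genes (0.0450, adjusted p = 0.675 with an estimated correlation; 0.0754 with the mouse as a block), ribosomal protein genes (0.0450, adjusted p = 0.689 with an estimated correlation) and oxidative phosphorylation genes (0.0450, adjusted p = 0.675 with an estimated correlation). The medians of the last 2 lists, 0.29 and 0.39, turned to -0.11 and -0.24 without TMM scaling, where the median of all genes moved from -0.23 to -0.80. Endothelial genes were lower (0.0450, adjusted p = 0.546 with an estimated correlation; 0.0575 with the mouse as a block). The remaining lists had adjusted p between 0.0843 and 0.986, and Krt19 (2.86), Vim (-0.42) and Ptprc (1.94) had edgeR adjusted p of 0.426, 0.997 and 0.829. Of single genes edgeR called 0 of 19703, with 1990 at an unadjusted p under 0.05, while DESeq2 called 394 higher and 469 lower, and limma on means over cells called 84.

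EpCAM+ and GFP+EpCAM+ cells were compared to ask how EpCAM+ cells differ when the tumour label is also required. Epcam (893 against 1286 CPM; log2 difference -0.53, SE 1.10, edgeR adjusted p = 0.845) and Krt19 (1273 against 1519 CPM; -0.25, SE 1.21, adjusted p = 0.933) differed by less than their errors (n = 3 each). The endothelial receptor Tie1 had a log2 difference of 5.02 at 1.85 ± 2.44 against 0.0532 ± 0.0532 CPM, and was the only member of its list higher adjusted over the list alone, with Vwf at 2.42 and Kdr at 2.34. The lower Tie1 value lies under the gauge of stray DNA reads in GFP+EpCAM+ cells (0.0856 CPM per olfactory receptor gene, and 0.277 in EpCAM+ cells), so differences of scarce endothelial genes are uncertain here. Ier2, an immediate early gene, stood at 296 ± 65.2 against 1011 ± 251 CPM (-1.77), and the ribosomal protein gene Rps6 at 112 ± 25.7 against 402 ± 96.4 CPM (-1.85). Camera called endothelial genes higher (adjusted p = 0.0219, adjusted p = 0.570 with an estimated correlation). It called immediate early and heat shock genes (0.0219, adjusted p = 0.672 with an estimated correlation), ribosomal protein genes (0.0219, adjusted p = 0.672 with an estimated correlation) and unfolded protein response genes (0.0219, adjusted p = 0.651 with an estimated correlation) lower. MHC class I genes were lower (0.0258, adjusted p = 0.570 with an estimated correlation; 0.0792 with the mouse as a block), with the peptide transporter genes Tap2 and Tap1 at -4.91 and -4.12. The other lists had adjusted p of 0.0906 or more. Xbp1, Vim and Ptprc had log2 differences of -1.42, -0.59 and -1.28. Gene by gene, edgeR called 0 of 19703, with 2697 at an unadjusted p under 0.05, while DESeq2 called 386 higher and 796 lower.

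GFP+ cells of each metastatic site were compared with GFP+ cells of the primary tumours to ask what distinguishes spread tumour cells. In peritoneal cells the immediate early genes Fos, Dusp1 and Zfp36 stood at 1306 ± 1120, 612 ± 446 and 398 ± 367 CPM against 4513 ± 3269, 2667 ± 693 and 2040 ± 1670 CPM in primary cells (SD, n = 3 each), lower in 3 of 3 mice. Their log2 differences of -1.79, -2.12 and -2.36 did not pass edgeR's test over all genes (adjusted p = 0.839, 0.713 and 0.749). The hypoxia-regulated carbonic anhydrase Car9 stood at 0.548 ± 0.112 against 76.4 ± 95 CPM (-7.12, SE 1.95, adjusted p = 0.313), and the mucin Muc1 at 29 ± 36.2 against 617 ± 310 CPM (-4.41, SE 1.18, adjusted p = 0.313), which the block for the mouse called (-5.27, adjusted p = 0.00597). C1qa, a complement gene of macrophages, stood at 34.5 ± 57.9 against 0.219 ± 0.243 CPM (7.28, SE 2.16, adjusted p = 0.391), higher in 3 of 3 mice.

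In peritoneal cells camera called 8 of 31 lists with the preset correlation and 0 with an estimated one. Immediate early and heat shock genes (18 genes, median -1.52; adjusted p = 1.44e-13, adjusted p = 0.462 with an estimated correlation) were lower with 0 called adjusted over the list alone. Hypoxia and glycolysis genes (20; 2.92e-07, adjusted p = 0.521 with an estimated correlation) were lower with 1 called adjusted over the list alone, Car9, and the glucose transporter Slc2a1 and Ndrg1 had log2 differences of -3.40 and -2.70. Epithelial genes (20; 9.20e-05, adjusted p = 0.614 with an estimated correlation) were lower with 1 called adjusted over the list alone, Muc1, while Epcam stood at 293 ± 505 against 23.9 ± 17.3 CPM (3.62, and -2.90 with the mouse as a block), higher in 1 of 3 mice, and Spint1 at 3.86. Chemokine and inflammatory genes (19; 7.81e-04, adjusted p = 0.450 with an estimated correlation) were lower with 2 called adjusted over the list alone, the chemokine Ccl7 (-4.20) and the cytokine Tnf (-5.42), and Nfkbia had -2.48. Adhesion and invasion genes (21; 0.0423, adjusted p = 0.614 with an estimated correlation) and fibroblast genes (16; 0.00606, adjusted p = 0.712 with an estimated correlation; 0.0758 with the mouse as a block) were lower, with Pdpn, Bgn and Col1a2 at -5.35, -1.97 and 1.45.

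Macrophage genes (14, median 3.62; 0.0226, adjusted p = 0.712 with an estimated correlation) were higher with 4 called adjusted over the list alone, C1qa, Fcgr3 (4.72), Aif1 (5.38) and Ms4a7, as were MHC class II genes as a list (7; 0.0226, adjusted p = 0.614 with an estimated correlation). Pan-leukocyte genes had an adjusted p of 0.0515, and 0.0485 with the mouse as a block. Islet genes (9; 0.446) and erythroid genes (6; 0.277), tested only in the comparisons of sites, and the other lists were not called. Ptprc (0.95), Krt19 (-1.66) and Vim (-0.22) each had an edgeR adjusted p of 1.000 to 3 digits. Over all genes edgeR called 0 of 21988, with 1331 at an unadjusted p under 0.05, and 3 with the mouse as a block, while DESeq2 called 80 higher and 85 lower and limma on means over cells called 0. Without mouse 1, 2 or 3 edgeR called 1, 5 or 5.

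In kidney cells macrophage genes were higher as a list, with 8 of 14 higher adjusted over the list alone and a median of 4.60 (camera adjusted p = 1.67e-07, adjusted p = 0.546 with an estimated correlation). Fcgr3 stood at 158 ± 90.6 against 3.34 ± 3.62 CPM (n = 2 against 3; log2 difference 5.57), the protease Ctss at 5.77 and C1qa at 8.12 on the log2 scale. Pan-leukocyte genes were higher (1.67e-07, adjusted p = 0.546 with an estimated correlation) with 2 of 12 called adjusted over the list alone, Srgn (5.16) and Cd48 (4.85), the latter higher in 1 of 2 mice, and Fcer1g at 3.13. Neutrophil genes were higher (0.0310, adjusted p = 0.546 with an estimated correlation; 0.129 with the mouse as a block) with 0 called, and Csf3r, Clec4d and Cxcr2 had 4.75, 3.48 and 3.71, each higher in 1 of 2 mice. Fibroblast genes were lower (0.0131, adjusted p = 0.928 with an estimated correlation) with Lum called adjusted over the list alone at 103 ± 20.2 against 2291 ± 1906 CPM (-4.47), and Dcn and Pdgfrb at -2.50 and -2.70. The block also called epithelial (2.70e-05) and classical tumour genes (0.00127) higher and immediate early genes (3.65e-07) lower, each with adjusted p = 0.928 with an estimated correlation and no block. Acinar genes (0.0678), kidney tubule genes (0.225) and the other lists were not called, and Ptprc, Epcam, Krt19 and Vim had log2 differences of 3.33, 1.56, 0.56 and 0.39. The ribosomal RNA gene Rn45s took a median of 7.18% of counts in kidney and 3.18% in GFP+ primary cells. Among single genes edgeR called 0 of 21988, with 1297 at an unadjusted p under 0.05, 1 without mouse 1 and 5 without mouse 2, while DESeq2 called 124 higher and 94 lower and limma on means over cells called 5.

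In liver cells proliferation genes had a median of -3.12, and 3 of 26 were lower adjusted over the list alone: the mitotic kinase Aurkb at 1.47 ± 0.582 against 242 ± 187 CPM (n = 2 against 3; log2 difference -7.47, edgeR adjusted p = 0.170), Birc5 (-4.23) and Ube2c (-4.49). The block for the mouse called Aurkb, Birc5 and Ube2c over all genes (adjusted p = 0.00264, 0.0402 and 0.0194), and also Lum, Bgn and Col1a2 (2.68e-04, 0.0116 and 0.00446). Relative to a median of all genes of -0.61, camera called this list lower (adjusted p = 1.10e-09, adjusted p = 0.718 with an estimated correlation). Fibroblast genes (5.66e-08, adjusted p = 0.718 with an estimated correlation) were lower with 7 of 16 called adjusted over the list alone, among them Lum (-6.18), Bgn (-8.46) and Col1a2 (-5.37). Oxidative phosphorylation (8.64e-05), ribosomal protein (0.00187), hypoxia (0.0161), mesenchymal transition (0.0161) and immediate early genes (0.0241) were lower too, each with adjusted p = 0.718 with an estimated correlation. MHC class II genes (4.59e-04) and kidney tubule genes (0.0241) were higher, each with adjusted p = 0.718 with an estimated correlation. Adjusted over the list alone H2-DMa (6.45) and H2-Eb1 (5.89) were higher and Car9 (-6.76) and Ndrg1 (-4.49) lower, while H2-Ab1 (3.64), Bnip3 (-3.79), Cycs (-2.60), Cox7b (-2.66), Ndufb9 (-2.44), Rpl10a (-2.79), Rpl32 (-2.04) and Rplp0 (-1.68) did not pass. Hepatocyte genes (0.376) were not called, and Ptprc, Epcam, Krt19 and Vim had -1.17, 1.07, 1.55 and -1.36. Rn45s took a median of 9.08% of counts, a single cell gave 75.3% of the summed counts of mouse 2, and mouse 3 summed to 535494 counts. Of single genes edgeR called 0 of 21988, with 3132 at an unadjusted p under 0.05, and 46 higher and 63 lower with the mouse as a block; without mouse 1, 2 or 3 it called 23, 4 or 10, while DESeq2 called 540 higher and 631 lower and limma on means over cells called 5.

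In spleen cells epithelial genes had a median of -2.99 (camera adjusted p = 1.63e-05, adjusted p = 0.992 with an estimated correlation). Muc1 was the member called adjusted over the list alone, at 7.90 ± 0.902 against 617 ± 310 CPM (n = 2 against 3; log2 difference -6.29, edgeR adjusted p = 0.384), lower in 2 of 2 mice. The keratin Krt18 (-3.56), the cadherin Cdh1 (-4.84), Krt19 (-3.16) and Epcam (-2.88) had negative log2 differences, Vim stood at 2898 ± 1248 against 1358 ± 777 CPM (1.09, adjusted p = 0.999), and Ptprc had -0.74. The block also called oxidative phosphorylation, hypoxia and ribosomal protein genes lower (0.046 each) and immediate early genes lower (1.69e-11), each with adjusted p = 0.992 with an estimated correlation and no block. Gene by gene, edgeR called 0 of 21988, with 1330 at an unadjusted p under 0.05, and 1 with the mouse as a block, while DESeq2 called 96 higher and 112 lower and limma on means over cells called 0.

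Against the mean of the 4 metastatic sites, primary GFP+ cells carried more RNA of 305 genes and less of 2. The stem cell receptor Lgr5 rose to 220.1 ± 226.3 CPM at the sites against 3.07 ± 2.80 CPM (SD over sums, n = 9 sums of 3 mice against 3). Its log2 difference was 5.27 (SE 1.33, edgeR adjusted p = 0.0186), and Fcgr4 rose by 6.78 (adjusted p = 0.0472). This fit has no block and counts the 9 sums as independent, although they come from 3 mice. Among the genes that fell were the glucuronidation enzyme Ugt2b5 (-9.10), Oscar (-8.74), the linker histone Hist1h1e (-7.34), Mcam (-6.65), the extracellular superoxide dismutase Sod3 (-6.44), Lix1 (-6.33), the transcription factor Batf (-6.09), Car9 (-5.48, adjusted p = 0.00316) and Lum (-3.18, adjusted p = 0.00792). With the mouse as a block Fcgr4 (3.04, edgeR adjusted p = 0.629) and Ugt2b5 (-2.98, adjusted p = 0.116) were not called. Of 100 groupings of the same sums that ignored the mouse, 33 gave as many calls, the real one included, and 0 genes were called among those of at least 10 CPM or with each cell weighted alike. These counts alone are therefore not evidence of a metastasis signature. Ptprc (0.59, adjusted p = 0.924), Epcam (0.84, adjusted p = 0.895; -0.75 with the block), Krt19 (-0.68, adjusted p = 0.886) and Vim (-0.02, adjusted p = 0.997) were not called by edgeR. With the mouse as a block 3 were higher and 127 lower, 87 of these among the 307, and 2 of 50 groupings within the mice gave as many calls, the real one included. Further, 184 passed without mouse 2, and DESeq2 called 73 higher and 158 lower.

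Across the mean of the sites camera called 11 of 31 lists with the preset correlation and 0 with an estimated one. Immediate early genes (3.66e-05, adjusted p = 0.648 with an estimated correlation) were lower with 0 called, with Fos, Dusp1 and Zfp36 at -1.70, -1.76 and -2.02, which edgeR called with the mouse as a block (adjusted p = 0.0488, 0.0146 and 0.00334), as it did Bgn (0.0140). Fibroblast genes (1.23e-04, adjusted p = 0.648 with an estimated correlation) were lower with 1 called, Lum, and 4 adjusted over the list alone, while Bgn (-2.94) and Fap (-2.95) were not called over all genes. Hypoxia genes (5.93e-04, adjusted p = 0.648 with an estimated correlation) were lower with 1 called, Car9, and 4 adjusted over the list alone, and the vasodilator peptide Adm and Ndrg1 had -4.56 and -2.61. Oxidative phosphorylation (0.00782, adjusted p = 0.772 with an estimated correlation), proliferation (0.0164, adjusted p = 0.779 with an estimated correlation) and chemokine genes (0.0362, adjusted p = 0.648 with an estimated correlation; 2 called, Ccl7 and Tnf) were lower. MHC class II genes (0.0225, adjusted p = 0.648 with an estimated correlation) were higher. Macrophage genes (0.00908, adjusted p = 0.670 with an estimated correlation; 0.0753 with the mouse as a block) and neutrophil genes (0.0457, adjusted p = 0.648 with an estimated correlation; 0.237 with the block) were higher, with Fcgr3 at 4.02, C1qa at 4.93 and Ms4a7 at 4.18. Pan-leukocyte genes were higher by camera (0.00908, adjusted p = 0.648 with an estimated correlation; 0.440 with the block), although their median was -0.19 and their mean 0.20, and 0.52 was their median without TMM scaling. Srgn had 4.19, Rac2 -2.91 and Arhgdib -1.55. Epithelial genes were lower (0.0247, adjusted p = 0.729 with an estimated correlation; 0.769 with the block). The block also called ribosomal protein (0.00999), tumour genotype (0.0328) and mesenchymal transition genes (0.0101) lower, with adjusted p of 0.915, 0.909 and 0.915 with an estimated correlation and no block.

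The 4 sites were compared with each other to ask whether tumour cells differ by the organ they reached. EdgeR called 198 of 21988 genes as different among sites, with 2769 at an unadjusted p under 0.05, and DESeq2 called 705. No gene was called among those of at least 10 CPM, 4 were called without mouse 2 and 34 without liver, and 25 of 100 groupings that ignored the mouse, the real one included, gave as many calls. A fit with the mouse as a block called 195, of which 87 were among the 198, and of 50 groupings within the mice only the real one gave as many. Groupings that differed only by swapped site names were counted apart, so fewer than 50 may be distinct.

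DNA coverage was compared per chromosome, as log2 of the coverage relative to each cell's autosomal mean, to set the copy number of tumour cells against leukocytes of the same tumours. In GFP+ cells coverage was lower than in CD45+ cells on chromosomes 4, 7, 9, 10, 12, 13 and 14 and higher on 2, 3, 5, 15 and 17, each in 3 of 3 mice. Chromosome 10 stood at -0.41 ± 0.03 in GFP+ and -0.04 ± 0.01 in CD45+ cells (SD, n = 3 each; difference -0.37, SE 0.0480, limma adjusted p = 8.82e-06), and chromosome 3 at 0.29 ± 0.14 against -0.06 ± 0.07 (0.35, SE 0.0707, adjusted p = 2.86e-04). The other lower chromosomes differed by -0.33 (4), -0.36 (7), -0.29 (9), -0.35 (12), -0.32 (13) and -0.33 (14), with limma adjusted p from 8.76e-05 to 0.00284. The other higher ones differed by 0.27 (2), 0.32 (5), 0.22 (15) and 0.16 (17), with adjusted p from 1.90e-04 to 0.0459; in cells of at least 50000 DNA reads chromosome 17 was not called (adjusted p = 0.0517), which left 11. Chromosome 19 (0.24) had an adjusted p of 0.112, and 0.0299 with the mouse as a block.

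EpCAM+ cells differed from CD45+ cells on 9 chromosomes: 2 (0.21), 3 (0.39) and 5 (0.19) were higher and 4 (-0.33), 7 (-0.27), 9 (-0.28), 10 (-0.33), 13 (-0.32) and 14 (-0.22) lower, with limma adjusted p from 4.64e-05 to 0.0147. GFP+EpCAM+ cells differed on 11: 3 (0.52), 5 (0.16), 17 (0.20) and X (0.44) were higher and 4 (-0.35), 7 (-0.31), 9 (-0.37), 10 (-0.35), 12 (-0.30), 13 (-0.31) and 14 (-0.31) lower, with adjusted p from 7.58e-06 to 0.0325. Chromosome 18 (0.23) had an adjusted p of 0.0978, and 0.0233 with the block. Each called difference had the same direction in 3 of 3 mice, and the 3 comparisons share the CD45+ cells. With the median over autosomal bins as each cell's centre 0, 0 and 2 chromosomes were called in GFP+, EpCAM+ and GFP+EpCAM+ cells, and with the median over bins of a chromosome 0, 0 and 6, where chromosomes 5 (-0.15) and 17 (-0.01) changed direction in GFP+EpCAM+ cells. Without mouse 3 the count in GFP+EpCAM+ cells was 7. In cells of at least 50000 DNA reads chromosome 5 was not called in EpCAM+ (limma adjusted p = 0.0762) or GFP+EpCAM+ cells (adjusted p = 0.137), which left 8 and 10.

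**Figure D2:**
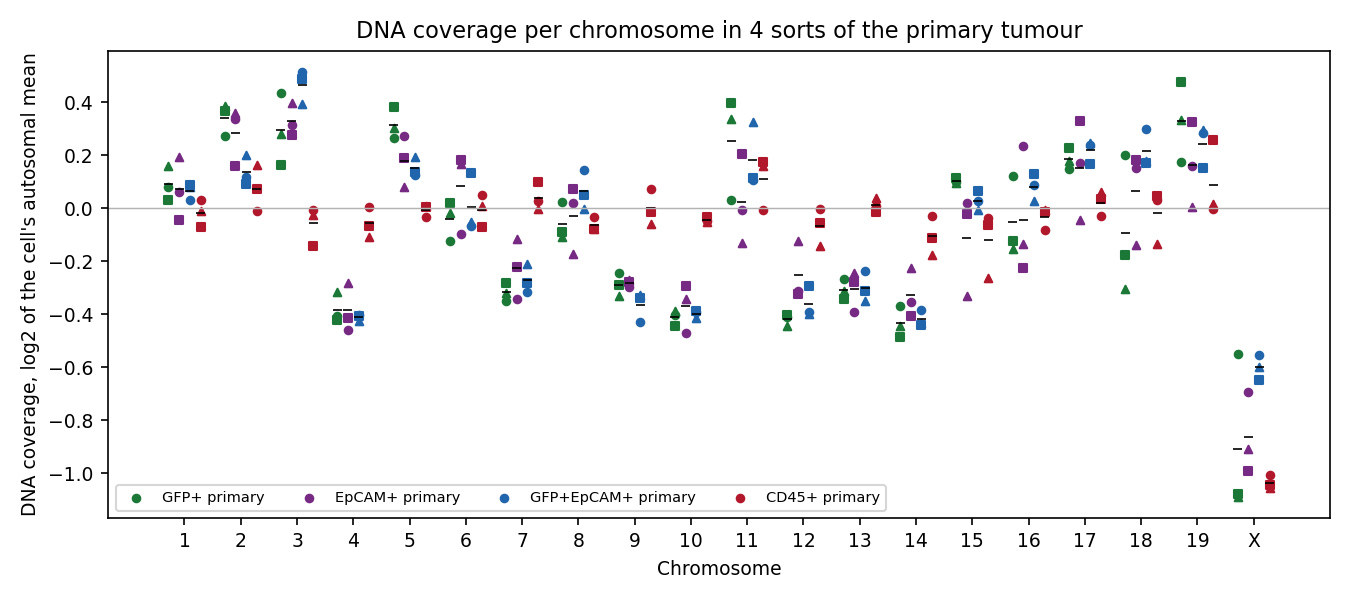
DNA coverage per chromosome as log2 of the ratio to each cell's autosomal mean, in the 4 sorts of the primary tumour; points are mice and dashes means over 3 mice. In the 3 sorts other than CD45+ chromosome 10 lies near -0.4 (-0.41 in GFP+ cells) and chromosome 3 above 0 (0.29 in GFP+ cells), while CD45+ autosomes lie near 0 and their X at -1.04.

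The score of a cell was the correlation of its DNA profile with the difference between GFP+ and CD45+ cells of the other mice. It averaged 0.260 ± 0.0294 in GFP+, 0.175 ± 0.108 in EpCAM+, 0.298 ± 0.0567 in GFP+EpCAM+ and -0.0545 ± 0.0797 in CD45+ cells (SD, n = 3 each). The differences from CD45+ cells were 0.314, 0.230 and 0.352, each with an exact two-sided permutation p of 0.1, the smallest that 3 mice against 3 allow. EpCAM+ and GFP+EpCAM+ cells differed from GFP+ cells by -0.0845 and 0.0379 (exact p = 0.3 and 0.4). In cells of at least 50000 DNA reads these differences were -0.141 (exact p = 0.1) and -0.003. The scores of peritoneum (0.292 ± 0.0785, n = 3), kidney (0.217 ± 0.167, n = 2), liver (0.165 ± 0.036, n = 2) and spleen cells (0.303 ± 0.103, n = 2) differed from GFP+ primary cells by 0.0321, -0.0423, -0.095 and 0.0434 (exact p = 0.6, 0.8, 0.2 and 0.8; the smallest possible for 2 against 3 is 0.2).

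Among the 318 cells with at least 50000 DNA reads, a score over chromosome means above 0.171, the 95th percentile of CD45+ cells, was taken as the tumour pattern. It was present in 25 of 26, 13 of 14 and 23 of 23 GFP+ cells of mice 1, 2 and 3, and in 10 of 10, 8 of 8 and 9 of 9 GFP+EpCAM+ cells. Among EpCAM+ cells it was present in 9 of 10, 5 of 6 and 2 of 6 (33.3%, exact Clopper-Pearson 95% interval 4.33 to 77.7%). By construction few CD45+ cells passed, 0 of 22, 2 of 18 and 1 of 13. In peritoneum 34 of 35, 17 of 17 and 20 of 22 cells carried the pattern. In mice 2 and 3 it was present in 20 of 20 and 15 of 20 kidney cells (75%, interval 50.9 to 91.3%), 5 of 5 and 5 of 5 liver cells, and 12 of 13 and 16 of 16 spleen cells.

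Coverage of the sex chromosomes was compared among the sorts. The X ratio to the autosomal mean was 0.5004 ± 0.0044 in CD45+ and 0.711 ± 0.0215 in GFP+EpCAM+ cells (SD, n = 3 mice each; difference 0.211, exact p = 0.1), and in EpCAM+ cells it was 0.538 ± 0.089 (difference 0.0378, exact p = 0.7). In GFP+ primary cells it was 0.702 in mouse 1, 0.485 in mouse 2 and 0.484 in mouse 3. The labels number the GFP+ primary cells of mouse 1 in another series than most of its other cells, so a batch cannot be separated from the sort there. In mouse 2 too the numbers of GFP+ primary cells overlap those of CD45+, liver and spleen cells and of some GFP+EpCAM+ and kidney cells. Whether such series are batches is not stated. A batch may therefore enter the RNA and DNA comparisons of GFP+ primary cells with the other sorts, CD45+ cells among them, and with the sites. The Y ratio was 0.570 ± 0.107 in CD45+, 0.403 ± 0.0955 in EpCAM+, 0.234 ± 0.114 in GFP+EpCAM+ and 0.140 ± 0.154 in GFP+ cells, with an exact p of 0.1 for GFP+ and for GFP+EpCAM+ cells against CD45+ cells. In peritoneum it was 0.0373 ± 0.0237. A Y ratio under 0.1 was found in 5.13 ± 8.88% of CD45+, 66.5 ± 34.3% of GFP+ and 94.1 ± 3.12% of peritoneum cells (n = 3 each; exact p = 0.1 for each against GFP+ cells). Among GFP+ primary cells the share was 26.9% in mouse 1, 85.7% in mouse 2 and 87% in mouse 3. In mice 2 and 3 it was 14 of 20 and 13 of 20 kidney cells, 2 of 5 and 5 of 5 liver cells, and 13 of 13 and 16 of 16 spleen cells. The Y ratio rests on 3 bins.

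**Figure D3:**
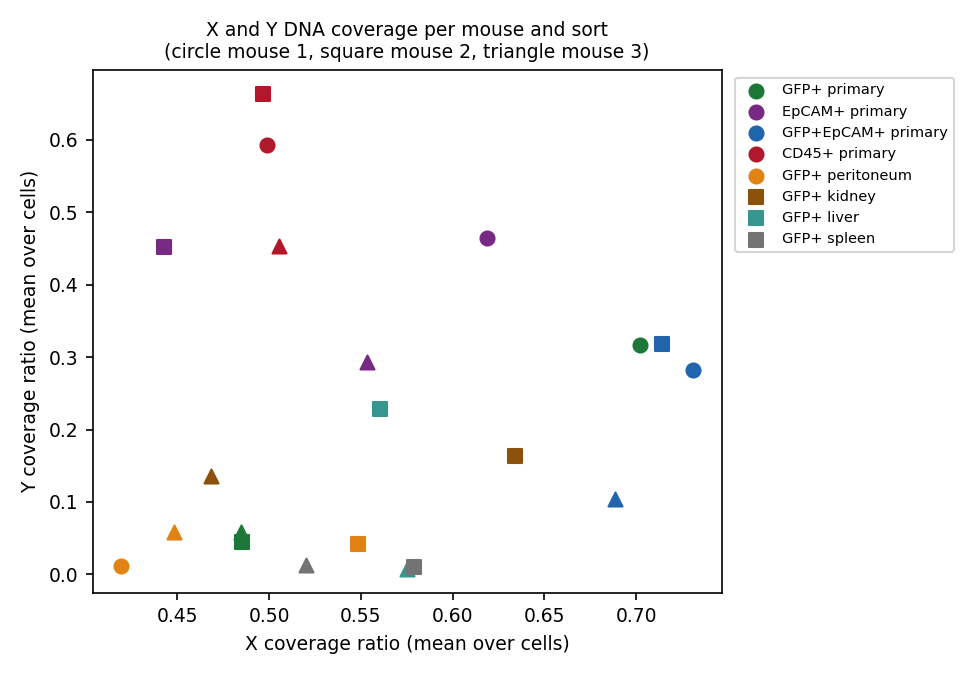
Mean X ratio against mean Y ratio to the autosomal mean, for each mouse and each of the 8 groups, in cells with at least 50000 DNA reads. CD45+ cells lie near an X ratio of 0.5 with Y ratios from 0.454 to 0.663, GFP+EpCAM+ cells at X ratios from 0.688 to 0.731, and peritoneum cells at Y ratios of 0.0115 to 0.058.

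Coverage per chromosome of metastatic cells was compared with GFP+ primary cells to ask whether copy number differs by site. On chromosome 10 peritoneum cells stood at -0.43 ± 0.01 and primary cells at -0.41 ± 0.03, and on chromosome 5 at 0.29 ± 0.06 and 0.32 ± 0.06 (SD, n = 3 each). Chromosome 6 differed most by p, with 0.15 ± 0.02 against -0.04 ± 0.07 (difference 0.19, SE 0.0924, limma adjusted p = 0.562), higher in 3 of 3 mice. Limma called 0 of 20 chromosomes for peritoneum, for the mean of the 4 sites and among the sites, with 0 at an unadjusted p under 0.05 in each, and no other tool was run. No alternative called a chromosome, although up to 2 had an unadjusted p under 0.05, and chromosome 6 differed by 0.16 for the mean of the sites. Means over mice hide larger differences in mouse 1. There peritoneum cells stood at -0.01 against -0.41 in primary cells on chromosome 12, -0.33 against 0.02 on 8 and -0.34 against 0.20 on 18. On chromosome 12 mouse 2 had -0.45 against -0.41 and mouse 3 had -0.45 against -0.45, and on 8 and 18 these mice also differed less. The bulk libraries of mouse 1 titled GFP+ went the same way, peritoneum against primary. They stood at 0.02 against -0.32 on chromosome 12, -0.314 against 0.061 on 8 and -0.327 against 0.295 on 18. The sort of that primary bulk is uncertain, since its label names EpCam. Differences within 1 mouse were not tested, so copy number by site stays open.

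Expression was compared with copy number over chromosomes because RNA and DNA were read from the same libraries. Both are group values, and their sets of cells and weights differ. In GFP+ cells expression rests on the summed counts of 76 cells past the RNA filter, and DNA on means over 94 cells. The 7 chromosomes with lower DNA coverage in GFP+ than CD45+ cells formed a set of their own, with a median expression difference of -0.53 and a median DNA difference of -0.33, against 0.10 and 0.15 for the 13 others. Chromosome 7 had a median expression difference of -0.99 over 1650 genes and a DNA difference of -0.36, and chromosome 3 had 0.27 over 946 genes and 0.35. Departures from a common line were largest for chromosome 7, whose expression lay below it, and chromosome 8 (0.14 against 0.0048), which lay above it. Chromosome 17 (-0.23 against 0.16) and chromosome 6 (-0.44 against -0.04) departed less. Within the 7, Pearson r was 0.254 (exact permutation p = 0.596) and Spearman rho -0.0714 (exact p = 0.906). Within the 13, r was 0.681 (permutation p = 0.0111) and rho 0.725 (permutation p = 0.00682), and with Benjamini-Hochberg adjustment over the 2 sets the adjusted p of r were 0.596 and 0.0222. Over the 20 together, as planned, r was 0.898 and rho 0.880 (permutation p = 1e-05, the smallest that 100000 permutations give), and r was 0.890 without chromosomes 10 and 3. That pooled value rests in part on the gap between the sets, and chromosomes are not independent replicates.

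**Figure D4:**
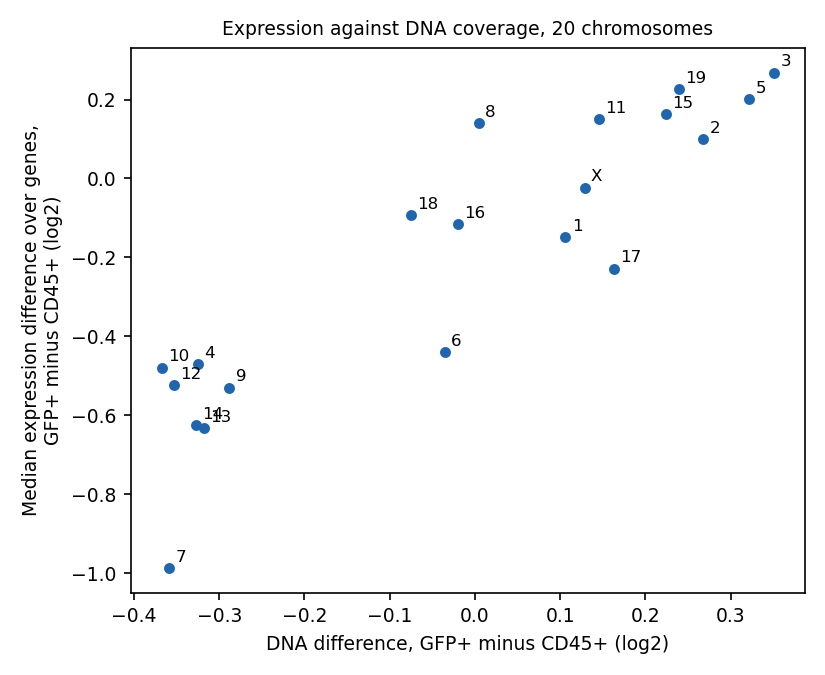
Median log2 expression difference against log2 DNA coverage difference, GFP+ minus CD45+ cells, for 19 autosomes and X. The 7 chromosomes with lower DNA coverage lie at expression differences of -0.99 to -0.47, and chromosome 3 at 0.27.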

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

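The tests chosen only after the result was seen were all groupings except those of the 4 sites that ignored the mouse, the fit without liver, the tests of X and Y coverage, those of genes of at least 100 CPM, those within 2 sets of chromosomes, and those of leukocyte RNA in kidney cells.

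The 198 genes that differed among the 4 metastatic sites were unlooked for, since each site had 0 genes called against the primary tumour. Of 100 groupings of the same sums that ignored the mouse, the real one included, 25 gave as many calls, with a median of 68 and a highest of 518 for the others, so chance was not excluded there. With the mouse as a block 195 were called and 1 of 50 groupings within the mice gave as many, the real one, with a highest other of 127. Groupings that differed only by swapped site names were counted apart, so fewer than 50 may be distinct and the share may be larger. With that limit, the result argues against chance for the 195, of which 87 are among the 198. The liver sums rest on few cells in both mice and 34 genes were called without liver, so the sparse liver libraries may be a source and organ effects stay open.

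For the mean of sites, 33 of 100 groupings that ignored the mouse, the real one included, gave at least the 307 calls found, with a median of 236 and a range of 10 to 910 for the others. With the mouse as a block 130 were called and 2 of 50 groupings within the mice gave as many, the real one included, with a highest other of 155, above the real count. Each other grouping also reassigned the site labels within a mouse, so its count depends on differences among the sites as well. These groupings therefore cannot decide on chance for the calls made with the block, of which 87 are among the 307. In addition, 0 genes of at least 10 CPM were called without the block, and 3 with the block on means over cells.

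For comparisons of 3 against 3 mice only 10 groupings exist, the real one included, too few for a share under 0.05. CD45+ against GFP+ cells gave 160 calls and the highest other grouping 2, or 0 among the 3 others that part all pairs of the same mouse (1 of 10 as large). EpCAM+ against GFP+, GFP+EpCAM+ against GFP+ and EpCAM+ against GFP+EpCAM+ cells gave 0 with a highest other of 0 (10 of 10 each), and peritoneum gave 0 with a highest other of 16, or 1 among those that part all pairs (10 of 10). For DNA, GFP+, EpCAM+ and GFP+EpCAM+ cells gave 12, 9 and 11 chromosomes and the other groupings 0 (1 of 10 each). Peritoneum gave 0 with a highest other of 0 (10 of 10), and the mean of sites 0 with a highest other of 2 (100 of 100, the real one included).

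The 5 bulk libraries other than CD45+ had tumour DNA pattern scores that were not part of a comparison. The scores were 0.755 for GFP+ primary cells of mouse 1, whose label names EpCam where its title names GFP so that its sort is uncertain, 0.671 for GFP+ primary cells of mouse 2, 0.598 for GFP+ peritoneum, 0.45 for GFP-negative primary and 0.167 for GFP-negative peritoneum cells, against -0.006 for the CD45+ bulk. The GFP-negative primary bulk has 19523 DNA reads, so tumour cells without the label may be present but its score is the least certain. The limit used for single cells was 0.171.

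GFP+EpCAM+ cells lay apart from CD45+ cells in X and Y, and GFP+ cells in Y, with no overlap of mouse means; host cells in the gate would give GFP+EpCAM+ cells the X of CD45+ cells, but their X ratio was higher by 0.211, while that of EpCAM+ cells was higher by 0.0378 (exact p = 0.7), so host cells in the EpCAM+ gate stay open. Too few reads would also remove Y from CD45+ cells, but 3.77% of them (2 of 53, 95% interval 0.46 to 13%) had a Y ratio under 0.1, against 94.6% in peritoneum (70 of 74). These intervals pool the mice, and both CD45+ cells were of mouse 3 (2 of 13, interval 1.92 to 45.4%). Cells were not matched for depth, with a median DNA total of 773082 in CD45+, 602993 in peritoneum and 276652 in GFP+ primary cells before filtering. The test is therefore less firm for mouse 3 and for GFP+ primary cells. Uneven amplification of Y stays open. RNA of 4 Y genes followed the Y ratio with Spearman rho of 0.792, 0.453 and 0.438 in mice 1, 2 and 3 (71, 75 and 95 cells). But so did 5 silent Y genes (0.717, 0.355 and 0.439), and the 4 stood 34.3, 297 and 5.08 times above these. The largest cell of each gene gave 66.3%, 86.3% and 44.3% of the counts of the 4 genes, and 30, 34 and 22 cells had any. The summed folds thus lean on few cells, and stray DNA reads are not set aside in any mouse. A candidate explanation is that the line held cells with and without the Y, for which the chromosome 18 ratio may serve as a second mark: its rho with Y was 0.708, 0.551 and 0.402, and 0.536, 0.716 and 0.605 within GFP+ primary cells. Within GFP+EpCAM+ cells the rho of chromosome 18 with Y was -0.236, 0.429 and 0.469 (10, 8 and 9 cells). Over all GFP+ cells the X ratio had a rho with Y of 0.692, 0.0731 and 0.154 (71, 77 and 95 cells). Host cells carry the Y too, so the relation alone does not part these cases. However, 10 of 10, 8 of 8 and 9 of 9 GFP+EpCAM+ cells carried the tumour pattern, and only 3, 3 and 5 had a Y ratio under 0.1. In GFP+ primary cells of mouse 1 the pattern was present in 25 of 26 and a Y ratio under 0.1 in 7 of 26. These values argue against host cells as the main source of the Y in those cells. For the other groups the question stays open.

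Over the 20 chromosomes together expression differences followed DNA differences, but within the 7 with lower coverage r was 0.254 (exact permutation p = 0.596). Stray DNA reads counted as exonic could give such a relation, because GFP+ cells held fewer DNA reads per RNA read than CD45+ cells by the olfactory receptor gauge (0.190 against 0.742 CPM per gene). Among genes with a mean of at least 100 CPM Pearson r over the 20 was 0.783, and among those of at least 100 CPM in both groups, far above that background, 0.736, which argues against stray reads as the source of the pooled relation. Within the 7 and the 13 others r was 0.532 (exact permutation p = 0.228) and 0.387 (permutation p = 0.193) in the first set of genes, and 0.610 (exact permutation p = 0.144) and 0.479 (permutation p = 0.0980) in the second, so a relation within these sets stays open.

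GFP+ kidney cells carried leukocyte RNA, among it Lyz2 at 1081 ± 1513 CPM, Fcgr3 at 158 ± 90.6 CPM and Fcer1g at 108 ± 82.7 CPM (n = 2 mice). GFP sorting would remove unlabelled leukocytes. The SD of Lyz2 exceeds its mean, so its level rests on 1 of the 2 mice. No gene of the pan-leukocyte and macrophage lists is in another list. Host leukocytes in the gate may be the source. The tumour pattern was present in 20 of 20 kidney cells of mouse 2 and 15 of 20 of mouse 3, so cells without it were seen in mouse 3 only. Leukocyte RNA fell with the tumour pattern score with a mean rho of -0.315 over 2 mice. The rho was -0.101 in mouse 2 and -0.529 in mouse 3 (20 cells each), and 0.113 and 0.574 with the Y ratio, so the 2 mice differ and the question stays open.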

How the results depend on the processing

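In each paragraph the settings with the mouse block on means over cells, cells of at least 50000 DNA reads, genes of at least 100 CPM (on average or in both groups), scores in pairs and liver left out were chosen only after the result was seen; all other tests were planned.

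CD45+ against GFP+ cells gave 160 genes, and 1915 with DESeq2 (917 higher, 998 lower), 270 of at least 10 CPM, 224 without TMM, 924 with means over cells of log2(CPM+1) (264 higher, 660 lower), 1279 with log2(CPM+0.1) (192 and 1087) and 1359 with the block on means. Without a mouse the count ran from 11 (without 3) to 151, with 38 without mouse 2. EpCAM+ against GFP+ cells gave 0, and 870 with DESeq2, 4 with means, 3 with log2(CPM+0.1), 21 with the block on means and 26 with only these groups. GFP+EpCAM+ against GFP+ cells gave 0, and 863, 84, 67, 107 and 13 in that order, 2 without TMM and 0 to 3 without a mouse. EpCAM+ against GFP+EpCAM+ cells gave 0, and 1182 with DESeq2, 1 with means and 7 with the block on means.

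Peritoneum gave 0 genes, and 165 with DESeq2, 18 without TMM, 6 with no gene filter, 3 with the block, 3 with the block on means and 1 to 5 without a mouse. Kidney gave 0, and 218 with DESeq2, 14 without TMM, 5 with means, 6 with the block on means, 10 with only these groups and 0 to 5 without a mouse (1 without mouse 1, 5 without mouse 2). Liver gave 0, and 1171 with DESeq2, 28 without TMM, 14 with no gene filter, 109 with the block, 5 with means, 102 with the block on means, 11 with only these groups and 4 to 23 without a mouse. Spleen gave 0, and 208 with DESeq2, 17 without TMM, 1 with the block, 3 with the block on means and 1 with only these groups.

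The mean of sites gave 307 genes, and 231 with DESeq2, 190 without TMM, 0 of at least 10 CPM, 130 with the block, 0 with means, 0 with log2(CPM+0.1), 3 with the block on means, 243 with liver left out (6 higher, 237 lower) and 184 to 311 without a mouse. Differences among the sites gave 198, and 705 with DESeq2, 431 with no gene filter, 0 of at least 10 CPM, 6 with means, 0 with log2(CPM+0.1), 100 with the block on means, 390 with only these groups, 34 with liver left out and 4 (without mouse 2) to 434 without a mouse.

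With an estimated correlation 5 lists were called for CD45+, 0 for EpCAM+ and 2 for GFP+EpCAM+ against GFP+ cells, and 0 elsewhere. Fry called 7 lists for CD45+ (macrophage, pan-leukocyte, MHC class II, T and natural killer cell, neutrophil, fibroblast and ribosomal protein genes), 1 for GFP+EpCAM+ against GFP+ cells (epithelial) and 0 elsewhere. With the block 5 were called for spleen. Beside the results are given the named genes, lists and chromosomes whose call the block changed, and it changed no other call among these. It kept 126 of the 160 genes of CD45+ against GFP+ cells in a total of 137. DNA calls went from 12, 9 and 11 to 11, 8 and 10 in cells of at least 50000 reads, 15, 8 and 13 without unstable bins (8, 4 and 7 higher), 12, 7 and 9 without the noisiest cells, 0, 0 and 2 with the median as centre, and to 0, 0 and 6 with the median per chromosome; in cells of at least 50000 reads both settings gave 0 for each. There chromosomes 5 (-0.15, and -0.10 in deep cells) and 17 (-0.014) of GFP+EpCAM+ cells reversed. The median standard error rose from 0.0689 to 0.214 and 0.208, and the median shift over chromosomes was 0.187 and -0.225 in GFP+EpCAM+ cells. With the median as centre an offset shared by the chromosomes of a cell is built in, so r with the main values is no evidence there. With the median per chromosome r was 0.961 or more, and 0.9557 or more in deep cells. That setting may mainly add a shared offset, although chromosomes 5 and 17 reversed. GFP+EpCAM+ cells gave 7 (without mouse 3) to 11 without a mouse. The score of GFP+EpCAM+ minus GFP+ cells went from 0.0379 to -0.003 in deep cells and that of EpCAM+ minus GFP+ cells from -0.0845 to -0.141 (exact p = 0.1); on autosomes only peritoneum went from 0.0321 to 0.0657 (exact p = 0.1), and with chromosome means peritoneum went from 0.0321 to -0.0473 and spleen from 0.0434 to -0.0184. Scores in pairs of the same mouse, as a block, differed by 0.314, 0.230 and 0.352 from CD45+ cells in 3 of 3 mice (exact p = 0.25, the smallest for 3 pairs). Against GFP+ primary cells EpCAM+ cells were lower in 3 of 3 mice and GFP+EpCAM+ cells higher in 3 of 3 (exact p = 0.25 each), peritoneum was higher in 2 of 3 (0.5), and kidney, liver and spleen differed by -0.0427, -0.0954 and 0.043 in 2 pairs (exact p = 1, 0.5 and 1). The cause of the other shifts was not tested.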

Other observations

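The genes in this part were chosen only after their values were seen, and no further tests were run on them.

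In CD45+ against GFP+ cells the secreted phosphoprotein Spp1 fell by 3.79 on the log2 scale, at 1831 ± 1273 against 25379 ± 2414 CPM (SE 0.759, edgeR adjusted p = 0.0104, lower in 3 of 3 mice). The cell cycle inhibitor Cdkn2b fell by 7.43 (1.83 ± 0.350 against 315 ± 89.8 CPM, adjusted p = 0.0154), while Cdkn2a (-5.90, adjusted p = 0.170), Trp53 (-2.10, 0.491) and Smad4 (-2.66, 0.412) did not pass. Haptoglobin, Hp, rose by 10.68 (702 ± 1087 against 0.424 ± 0.220 CPM, adjusted p = 0.0104), and the cytokine Il1a by 10.48 and the chemokine Ccl5 by 10.68. The chemokines Ccl7 (-4.80, 122 against 3374 CPM, adjusted p = 0.126) and Cxcl1 (-4.01, 85.4 against 1372 CPM, adjusted p = 0.133) were lower only when adjusted over the list alone.

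In peritoneum the isomerase Agr2 had a log2 difference of 8.13 (65.6 against 0.231 CPM, higher in 3 of 3 mice) and in spleen the protease Ctse had -7.10, Anxa10 -6.65 and Mmp7 -8.93, each called only when adjusted over the list alone. In the mean of sites Mmp7 (-6.54), Anxa10 (-5.52), Ccl7 (-3.19) and Tnf (-4.81) were called lower over all genes. That fit has no block and counts the sums of a mouse as independent. Of 100 groupings that ignored the mouse, 33 gave as many calls, the real one included, so these calls are uncertain. In kidney the acute phase gene Saa3 (7.07) and the protease Mmp10 (8.37) were called only when adjusted over the list alone.

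Among shallow libraries, peritoneum cell 40 of mouse 2 had an RNA correlation of 0.881 with cell 45 of the same group, kidney cell 52 had 0.829 with peritoneum cell 57, and peritoneum cell 36 had 0.829 with CD45+ primary cell 24 (0.409 with the next best), which bears on leukocyte RNA in GFP+ cells. In all 6 of 43 shallow libraries passed 0.8, and whether they share reads with the deeper libraries was not tested.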
